A study of Homo sapiens with 19 samples.

How the data were processed

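Gene expression was measured in 19 samples of A549 cells, a human lung adenocarcinoma line, each hybridised to 1 array of an Illumina HumanRef-8 v3 BeadChip. Cells were not infected (NI), or carried a non-silencing hairpin (shNS) or a hairpin against G9a (shG9a). G9a is the histone H3 lysine 9 methyltransferase encoded by EHMT2. RNA came from cells without dexamethasone (0 h) or after 24 h with 100 nM of this synthetic glucocorticoid. The groups held 3 arrays each, except NI at 24 h with 4. The labels say nothing of separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicate numbers follow the order of deposit and pair no samples by themselves.

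Per the file headers, the deposited table of non-normalised values gave for each probe and array the mean bead intensity on a linear scale, with control probes included. Its values had not been background-subtracted: the median of the negative control probes lay between 95.4 and 146. The deposited detection p-value of each probe was computed against the negative controls of the same array, per the file headers. The scanner software is not given in the sources used here. A separate deposited table held values on the log2 scale processed by the authors for 22011 probes; limma is named in the submitters' processing notes, without a version. Those log2 values correlated with the normalised values computed here at 0.99995 on every array, with array medians between 6.93 and 6.96, a median 0.044 to 0.045 above the values computed here and the same direction. The filter behind the smaller number of probes is not given in the sources used here.

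From the bead intensities, neqc of limma 3.58.1 in R 4.3.3 corrected the background with the 664 negative control probes, added an offset of 16, normalised between arrays by quantiles and took log2. The 15 other control probes were left out. Of the 24525 regular probes, 19758 had 1 gene symbol in the platform annotation, none had several and 4767 had none listed. Symbols of 19740 probes were updated through gene identifiers of a GRCh38.p14 gene table and 18 were kept as given, which left 15550 distinct symbols. Genes with no listed probe were not analysed here. For each symbol the probe with the highest mean over all arrays was used, and it had to be detected (p under 0.05) on at least 3 arrays; 11750 genes remained. Where the text names a gene with other detected probes that changed in the opposite direction, it says so. No sample of the tables was left out. Tables were read with jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

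The median signal of the regular probes lay between 173 and 282 per array, or 1.82 to 2.10 times the median negative control. Between 15383 and 16298 probes (62.7% to 66.5%) were detected per array. The number of arrays limits the precision. Arrays of the same group correlated at 0.979 to 0.997, and no array was a copy of another.

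A linear model with a mean for each of the 6 groups was fitted to all 19 arrays with lmFit and eBayes of limma, so that the groups shared 1 estimate of the spread. Its moderated test gave 7 comparisons, each with Benjamini-Hochberg adjustment over the 11750 genes at 0.05: the dexamethasone change in NI, shNS and shG9a, the difference of the last pair of changes, shG9a against shNS at 0 h and at 24 h, and shNS against NI at 0 h. Every adjusted p of a gene comes from this limma test unless another is named. Genes responsive in NI (adjusted p under 0.05 and at least 1.5-fold) were tested for G9a dependence on shNS and shG9a arrays alone, so that the changes used for selection and those tested shared no array, while the spread came from all arrays. A gene not detected on any array of a group has only a bound there: its fold is given as "at least", from the other group's mean over the higher of the dim probe's own level and the lowest detected signal of each array.

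The gene lists and the rule for naming genes were chosen before the data were examined, as were the comparisons, their tests and all but a pair of the alternatives; some tests of explanations were chosen later, as the closing section states. The 28 lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, with camera at an estimated correlation and fry beside it. They cover the glucocorticoid response and its known branches, cell division, stress and metabolic pathways, chromatin, cell identity, housekeeping genes, and leukocyte, fibroblast and endothelial cells. Named genes are EHMT2, EHMT1 and NR3C1, up to 8 largest rises and 8 largest falls past the threshold with the same direction on every slide (for NI, on every 24 h array), and up to 4 members of each list with the smallest p, from which the text takes its examples. For G9a dependence, up to 5 genes per class past the threshold over the selected genes were to be named. Genes outside the rule are said to be so. A gene that the rule names at 24 h is not reported here.

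Slides 2, 3 and 4 held 1 array each of NI at 0 h and of the 4 hairpin groups. The NI arrays at 24 h lay on slides 1 and 5, with no other group. Deviations of arrays on the same slide from their group means correlated at 0.41, 0.30 and 0.33 for the pairs of shNS with and without dexamethasone, 0.49, 0.35 and 0.28 for those of shG9a, 0.42, 0.65 and 0.28 for shG9a with shNS at 0 h and 0.41, 0.42 and 0.28 at 24 h. They were -0.06, 0.47 and -0.01 for shNS with NI. The slide therefore paired the hairpin arrays with each other and not with the NI arrays; the pairing comes from the slide positions in the labels. Alternatives were the authors' values, no background correction, median scaling, no detection filter or a stricter one, every detected probe, the slide as a fixed or random block, array weights, a minimum fold, the compared groups alone and leaving out each array in turn. Only for NI were the 24 h arrays of slide 1 and of slide 5 also used separately, chosen after seeing the data.

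The procedure was tested on simulated data with the spread of these arrays, where 200 of 11750 genes were changed. Genes changed 1.5-fold, 2-fold and 4-fold were called in 40.3%, 77.6% and 100% of cases for dexamethasone in NI, in 43.3%, 82.1% and 100% for shNS, and in 31.3%, 65.7% and 95.5% for shG9a. For the difference of dexamethasone changes the shares were 11.9%, 44.8% and 89.4%. They were 28.4%, 82.1% and 98.5% for shG9a against shNS at 0 h, 38.8%, 71.6% and 100% at 24 h, and 38.8%, 79.1% and 98.5% for shNS against NI. In each of the 7 comparisons between 2 and 11 unchanged genes were called, camera called a changed list of 20 genes, and 0 unchanged lists were called. The simulated values were drawn independently for each gene and array, without slide effects or correlation between genes. These shares and counts therefore do not show how the tests behave where genes or arrays of a slide vary together.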

Results

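The samples were 19 arrays of A549 cells, an epithelial line from a human lung adenocarcinoma that carries the glucocorticoid receptor. Cells without virus (NI), with a non-silencing hairpin (shNS) or with a hairpin against G9a (shG9a) were compared before and 24 h after dexamethasone at 100 nM. NI had 3 arrays at 0 h and 4 at 24 h, and shNS and shG9a had 3 at each time. The series asks which glucocorticoid-regulated genes depend on G9a, the H3K9 methyltransferase that also acts as a coregulator of the glucocorticoid receptor. Expression was measured for 11750 genes. The median regular probe read 1.82 to 2.10 times the median negative control, and 62.7% to 66.5% of probes were detected per array. The first principal component held 48.9% of the variance and parted every array with dexamethasone from every array without, and the second held 11.0%. Changes are log2 differences with standard errors of the limma fit.

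EHMT2, the gene of G9a and the target of the hairpin, read lower on each of the 6 shG9a arrays (6.56 to 7.08) than on any of the 13 other arrays (7.43 to 7.96). Its mean was 6.89 ± 0.18 (SD, n = 6) with shG9a, 7.67 ± 0.18 (SD, n = 6) with shNS and 7.73 ± 0.17 (SD, n = 7) in NI. The shG9a level was 58.5% of the shNS level, or 1.71-fold lower (exact permutation test over 924 assignments, two-sided p = 0.0022). This test pools the arrays of both times and takes them as independent, although the slide pairs the hairpin arrays. Its p-value therefore does not allow for the slides. At 0 h EHMT2 fell by 0.82 on the log2 scale (SE 0.15, adjusted p = 0.034), and at 24 h the difference was -0.73 ± 0.15 (adjusted p = 0.066). With the slide as a block the adjusted p at 0 h was 0.066, and over all alternatives it ranged from 0.011 to 0.999. It was 0.226, 0.170 and 0.0696 without the shNS array 1, 2 or 3 at 0 h, and 0.196 and 0.0926 without the shG9a array 1 or 2, so that the call at 0 h held only with all of these arrays in the fit. EHMT1, which encodes the partner methyltransferase GLP, differed by 0.19 ± 0.20 at 0 h and 0.11 ± 0.20 at 24 h, and NR3C1, the glucocorticoid receptor gene, by -0.23 ± 0.17 and -0.11 ± 0.17. Neither passed the threshold in any comparison.

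**Figure D1:**
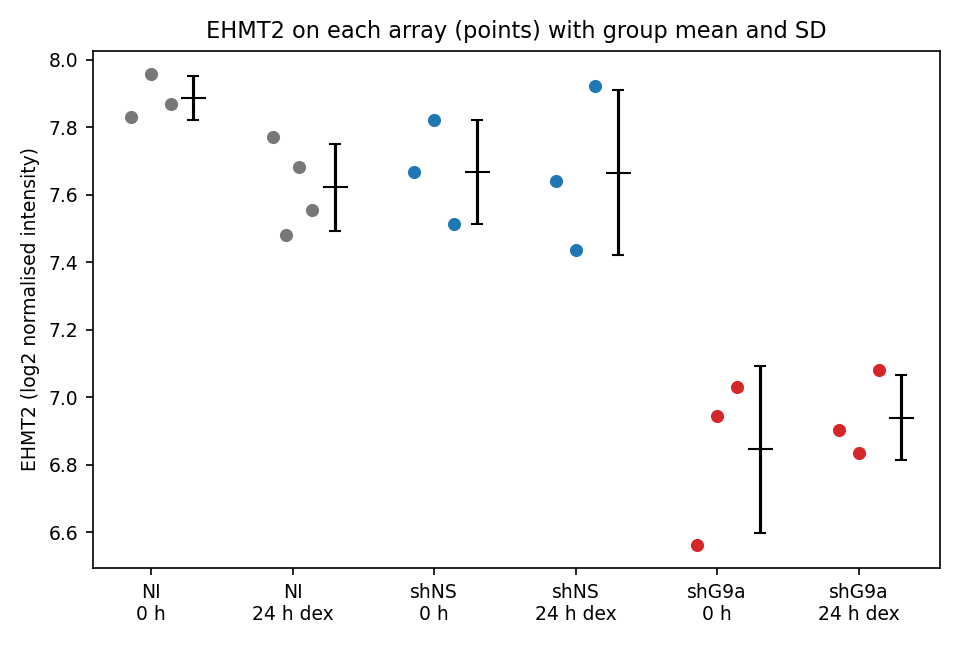
EHMT2 on each array as log2 normalised intensity, grouped by cell population and time, with the group mean and SD. The 6 shG9a arrays lie between 6.56 and 7.08, below the 13 other arrays at 7.43 to 7.96.

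Dexamethasone in uninfected cells shows the response without a viral vector. The largest rises after 24 h in NI (4 arrays against 3) were those of SERPINA3, an acute phase protease inhibitor (5.71 ± 0.38, adjusted p = 5.1e-09), CIDEC, a lipid droplet protein (4.88 ± 0.35, adjusted p = 1e-08) and ALOX5AP, the activator of leukotriene synthesis (4.27 ± 0.26, adjusted p = 1.6e-09). S100P (4.17 ± 0.42), PLA2G10, a secreted phospholipase (4.14 ± 0.34), MAOA, monoamine oxidase A (3.91 ± 0.16), VSTM2L (3.74 ± 0.30) and the aminopeptidase ANPEP (3.71 ± 0.16) followed. Cell division genes were among the largest falls: the spindle checkpoint gene MAD2L1 (-3.11 ± 0.20), the histone chaperone ASF1B (-2.96 ± 0.27) and the ribonucleotide reductase subunit RRM2 (-2.69 ± 0.46). The other large falls were those of VN1R2 (-3.26 ± 0.30), USH1G (-3.25 ± 0.23), FANCL (-3.13 ± 0.16), PGAM4 (-3.13 ± 0.14) and CHORDC1 (-2.98 ± 0.16). In shNS these 5 genes stood at -0.35 ± 0.32, -0.33 ± 0.25, -0.57 ± 0.17, -0.37 ± 0.15 and -0.76 ± 0.17, with FANCL and CHORDC1 past the threshold. The falls in NI coincide with slides 1 and 5, where the control probes for weakly matched binding read lower. EHMT2 (-0.26 ± 0.14), EHMT1 (-0.36 ± 0.19) and NR3C1 (-0.13 ± 0.16) did not pass; a second NR3C1 probe read 0.15.

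Of the 21 measured glucocorticoid-induced genes, 17 rose in NI (17 adjusted over the list alone), among them ANGPTL4, an inhibitor of lipoprotein lipase (3.25 ± 0.19), and the transcription factor ZBTB16, which was not detected at 0 h and rose at least 6.07-fold (adjusted p = 3.1e-10). KLF15, a list member known as a direct receptor target, fell (-1.50 ± 0.29, adjusted p = 8.2e-04), while it stood at 0.04 ± 0.31 in shNS. The list was higher as a whole (camera adjusted p = 1.6e-13, and adjusted p = 0.032 with an estimated correlation). Fasting metabolism genes rose in 12 of 14 cases (12 adjusted over the list alone), with ACSL1, a fatty acid activating enzyme (1.97 ± 0.19), and the lipid droplet gene PLIN2 (1.20 ± 0.14) as examples. For fasting genes camera gave adjusted p = 1.4e-08, and adjusted p = 0.076 with an estimated correlation. Acute phase and coagulation genes rose in 11 of 16 cases (13 over the list alone), including SAA1 (2.84 ± 0.29), complement C3 (2.18 ± 0.25) and LBP, the lipopolysaccharide binding protein (2.29 ± 0.30). For acute phase genes the camera result was adjusted p = 2.5e-07, and adjusted p = 0.078 with an estimated correlation. Metal-binding metallothioneins rose in 6 of 7 cases (6 over the list alone), as in MT1H (2.44 ± 0.21), MT1X (3.15 ± 0.35) and MT2A (2.38 ± 0.29). For metallothioneins the list test gave adjusted p = 7.2e-07, and adjusted p = 0.089 with an estimated correlation.

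Mitosis genes fell in 21 of 22 cases in NI (21 adjusted over the list alone), among them CDK1, the kinase that drives entry into mitosis (-1.99 ± 0.20), CCNA2 (-1.87 ± 0.19) and MKI67 (-1.86 ± 0.21). For mitosis genes camera gave adjusted p = 5.7e-19, and adjusted p = 0.078 with an estimated correlation. DNA replication genes fell in 19 of 20 cases (19 over the list alone), including POLE2 (-2.09 ± 0.20), the helicase subunits MCM5 (-2.30 ± 0.22) and MCM7 (-1.86 ± 0.20), and TYMS (-1.58 ± 0.17). For replication genes the camera result was adjusted p = 4.1e-18, and adjusted p = 0.078 with an estimated correlation. Cytokine and chemokine genes fell in 5 of 13 cases (6 over the list alone): CCL2 (-2.50 ± 0.43), CXCL5 (-1.62 ± 0.16), the cyclooxygenase PTGS2 (-1.31 ± 0.29) and LIF (-0.79 ± 0.16) were among them. For cytokines the list test gave adjusted p = 0.0051, and adjusted p = 0.078 with an estimated correlation. H3K9 methylation genes fell in 6 of 20 cases (6 over the list alone), with the heterochromatin proteins CBX1 (-1.58 ± 0.18) and CBX5 (-0.91 ± 0.15) and the DNA methyltransferase DNMT1 (-1.06 ± 0.14) as examples. For H3K9 genes camera gave adjusted p = 0.023, and adjusted p = 0.078 with an estimated correlation. Interferon-stimulated genes rose in 7 of 19 cases (7 higher and 1 lower over the list alone), including IFIT1 (1.83 ± 0.23) and EPSTI1, which was not detected at 0 h and rose at least 2.34-fold. For interferon genes the camera result was adjusted p = 0.015, and adjusted p = 0.13 with an estimated correlation.

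Other NI lists did not pass camera although members changed. The epithelial sodium channel subunits SCNN1B (2.71 ± 0.18) and SCNN1G (at least 7.24-fold from not detected) rose and SLC12A2 fell (-1.07 ± 0.31), while the median of the sodium and fluid transport list was -0.07 against a mean of 0.48; this median turned with the scaling, as did those of the circadian clock and housekeeping lists. In the surfactant list SFTPD, surfactant protein D (3.48 ± 0.25), and ABCA3 (0.84 ± 0.19) rose. HSD11B1, which makes cortisol from cortisone (at least 8.33-fold), and HSD11B2, which makes cortisone from cortisol (at least 5.22-fold), rose from not detected. E-cadherin CDH1 (1.43 ± 0.23) rose, as did SNAI2 (at least 2.80-fold), a repressor of epithelial genes. Receptor and coregulator, leukocyte, fibroblast, circadian and hypoxia lists had a median, mean and test that were not all of 1 sign. None of the 5 leukocyte, 4 fibroblast or 3 endothelial markers passed.

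In NI 3112 genes changed, 1714 higher and 1398 lower, of which 2191 by at least 1.5-fold. Array weights gave 6379 genes. Median scaling gave 2247 higher and 1024 lower, with a median change of all genes of 0.10 against 0.02 without it. Because the 24 h arrays fill slides 1 and 5 and the 0 h arrays slides 2 to 4, slide and dexamethasone cannot be told apart in NI, and a random block for the slide does not part them; the arrays of slide 1 alone gave 2538 genes and those of slide 5 alone 1991.

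**Figure D2:**
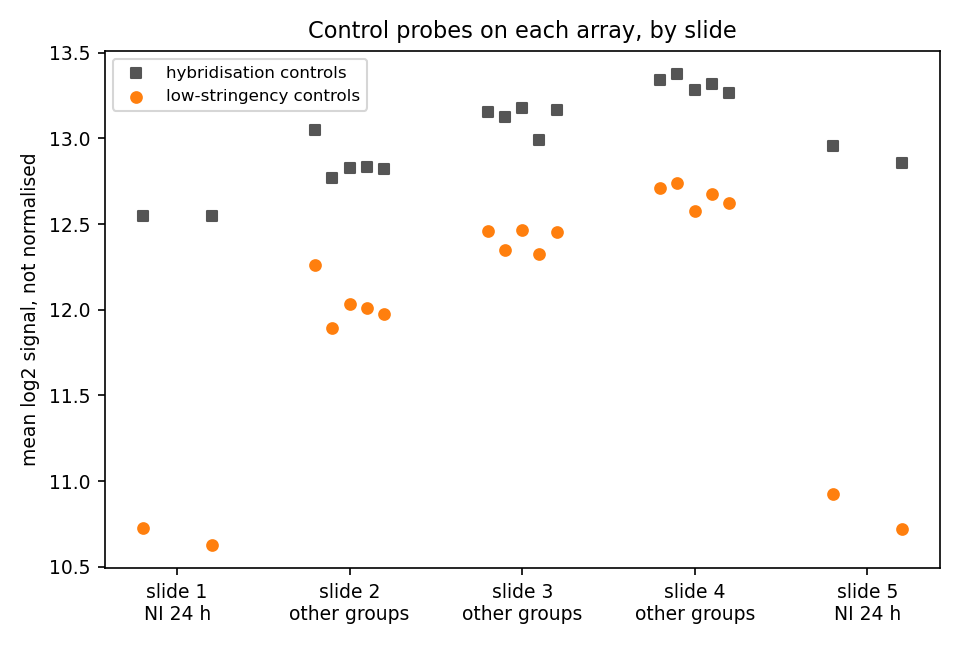
Mean log2 signal, not normalised, of hybridisation controls (squares) and low-stringency controls (circles) on each array, by slide. Relative to slides 2 to 4, the low-stringency controls differ by -1.62 and the hybridisation controls by -0.37 on slides 1 and 5, which hold the NI arrays at 24 h. Low-stringency controls are the 4 probes marked only as such. Probes marked as both kinds count among the 6 hybridisation controls and differ by -0.52 to -0.30.

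Dexamethasone with the non-silencing hairpin gives the response on slides that hold both times. SERPINA3 rose most in shNS (6.69 ± 0.41, adjusted p = 4.4e-09, 3 arrays against 3), followed by CIDEC (5.06 ± 0.37, adjusted p = 2.6e-08) and the metallothioneins MT1X (4.84 ± 0.38) and MT1G (4.26 ± 0.35). CDH16, a kidney-type cadherin, was not detected at 0 h and rose at least 16.7-fold (adjusted p = 1.1e-10). SFTPD (4.23 ± 0.27), ALOX5AP (4.05 ± 0.28) and CIDECP1, which is annotated as a pseudogene of CIDEC (3.92 ± 0.29), completed the 8 largest rises. Among the largest falls were the replication genes MCM10 (-2.76 ± 0.32), EXO1 (-2.59 ± 0.29), BLM (-2.54 ± 0.25) and DTL (-2.64 ± 0.35). TRIML2 (-2.85 ± 0.22), the mitotic helicase ERCC6L (-2.64 ± 0.30), HLA-DMB (-2.63 ± 0.46) and the cell cycle repressor E2F7 (-2.51 ± 0.27) also fell. EHMT2 (-0.00 ± 0.15), EHMT1 (0.00 ± 0.20) and NR3C1 (-0.17 ± 0.17, a second probe at 0.21) did not pass.

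Glucocorticoid-induced genes rose in 15 of 21 cases in shNS (17 adjusted over the list alone), including MAOA (3.89 ± 0.17), ANGPTL4 (2.88 ± 0.20), CIDEC (5.06 ± 0.37) and ZBTB16 (at least 5.14-fold from not detected). For glucocorticoid-induced genes the list test gave adjusted p = 3.1e-17, and adjusted p = 0.011 with an estimated correlation. Metallothioneins rose in 6 of 7 cases (7 over the list alone), as in MT1H (3.76 ± 0.22) and MT1E (3.61 ± 0.29), with adjusted p = 7.5e-13 (0.034 as the adjusted p with an estimated correlation). The same estimated-correlation p of 0.034 held for acute phase genes, 12 of 16 higher (15 over the list alone), with LBP (3.56 ± 0.32), C3 (2.92 ± 0.26) and SAA1 (at least 7.65-fold from not detected) as examples (adjusted p = 2e-11). It held for fasting metabolism genes, 8 of 14 higher (9 over the list alone), with ACSL1 (2.75 ± 0.21) and PLIN2 (1.03 ± 0.15; adjusted p = 1e-07). Mitosis genes fell in 21 of 22 cases (21 over the list alone), including CDK1 (-2.32 ± 0.21), AURKB (-2.13 ± 0.24) and TOP2A (-1.85 ± 0.21). For mitosis genes camera gave adjusted p = 9.2e-25, and adjusted p = 0.034 with an estimated correlation. DNA replication genes fell in 18 of 20 cases (18 over the list alone), with POLE2 (-2.20 ± 0.21), TYMS (-1.72 ± 0.18) and RFC3 (-2.28 ± 0.26) as examples. For replication genes the camera result was adjusted p = 6.8e-20, and adjusted p = 0.034 with an estimated correlation. NRF2 targets fell in 4 of 16 cases (8 over the list alone), among them the cystine carrier SLC7A11 (-1.03 ± 0.18) and NQO1 (-0.42 ± 0.13). For NRF2 targets the list test gave adjusted p = 0.0068, and adjusted p = 0.034 with an estimated correlation.

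A further 4 lists in shNS had a camera adjusted p of 0.03 that was lost with an estimated correlation. Surfactant genes SFTPD (4.23 ± 0.27) and ABCA3 (0.93 ± 0.21) rose, 2 of 5 members (2 over the list alone; adjusted p = 0.11 with an estimated correlation). In sodium and fluid transport, SCNN1B (2.94 ± 0.19), SCNN1G (at least 9.42-fold from not detected) and the kinase SGK1 (1.55 ± 0.21) rose and SLC12A2 fell (-1.28 ± 0.34), 3 of 10 higher and 1 lower (4 higher and 1 lower over the list alone; adjusted p = 0.11 with an estimated correlation, and 0.063 with the slide as a block). Cholesterol synthesis genes TM7SF2 (1.28 ± 0.25), LSS (1.04 ± 0.23) and MVD (1.21 ± 0.40) rose, 3 of 15 (4 over the list alone; adjusted p = 0.35 with an estimated correlation). Among cytokines and chemokines 5 of 13 fell and 1 rose (6 lower and 1 higher over the list alone): PTGS2 (-2.01 ± 0.31), CXCL5 (-1.40 ± 0.17) and LIF (-0.74 ± 0.17) fell, while CXCL2 rose (0.95 ± 0.26; adjusted p = 0.14 with an estimated correlation). In the list of matrix proteases and their inhibitors 4 of 12 members fell (4 over the list alone). They were PLAUR (-1.09 ± 0.18), MMP3 (-1.02 ± 0.19), MMP7 (-1.46 ± 0.44) and PLAT (at least 1.14-fold lower, to not detected). For this list camera gave adjusted p = 0.059 without and 0.046 with the slide as a block, and adjusted p = 0.11 with an estimated correlation.

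The remaining shNS lists did not pass camera. H3K9 methylation genes had 4 of 20 lower (4 over the list alone; adjusted p = 0.17), among them DNMT1 (-1.03 ± 0.15), and interferon-stimulated genes 3 of 19 higher (4 over the list alone; adjusted p = 0.18), among them IFIT1 (1.69 ± 0.25). In the circadian list CRY1 (-1.46 ± 0.17) and NR1D2 (-1.34 ± 0.35) fell and BMAL1 rose (0.62 ± 0.17), 5 of 16 changed (9 over the list alone; adjusted p = 0.73). MAP kinase feedback genes ERRFI1 (1.41 ± 0.20), the phosphatase DUSP1 (1.44 ± 0.23) and FOS (1.86 ± 0.34) rose and ETV4 fell (-1.38 ± 0.25), 7 of 18 changed (9 over the list alone; adjusted p = 0.72). Among p53 targets GDF15 (-2.27 ± 0.24) and DDB2 (-0.89 ± 0.17) fell and GADD45A rose (0.70 ± 0.15), 5 of 18 changed (5 over the list alone; adjusted p = 0.85). Epithelial keratins KRT8 (1.03 ± 0.16) and KRT7 (0.82 ± 0.13) and CDH1 (1.12 ± 0.25) rose, with 5 of 13 changed (7 over the list alone; adjusted p = 0.27). Mesenchymal SNAI2 (1.60 ± 0.31) and ITGA5 (0.92 ± 0.21) rose, 2 of 12 (2 over the list alone; adjusted p = 0.79). HSD11B1 (at least 9.01-fold from not detected) and HSD11B2 (2.75 ± 0.53) rose among 5 of 19 changed receptor and coregulator genes (5 over the list alone; adjusted p = 0.85).

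Serine synthesis genes in shNS held a rise of SHMT1 (1.04 ± 0.13) and falls of SLC7A11 (-1.03 ± 0.18) and ATF3 (-1.51 ± 0.33), 5 of 19 changed (6 over the list alone; adjusted p = 0.24). The autophagy receptor SQSTM1 fell (-1.05 ± 0.19) and WIPI1 rose (0.79 ± 0.18), 3 of 16 changed (3 over the list alone; adjusted p = 0.31). In the hypoxia list NDRG1 rose (1.72 ± 0.22) and EGLN1 fell (-0.73 ± 0.13), 2 of 13 changed (2 over the list alone; adjusted p = 0.85). Of the markers of other cell types, THY1 fell (-1.05 ± 0.27), 1 of 4 fibroblast genes (1 over the list alone; adjusted p = 0.54); none of 5 leukocyte (adjusted p = 0.79) or 3 endothelial markers (adjusted p = 0.85) passed. None of the 8 cancer-testis genes (adjusted p = 0.65) or 9 housekeeping genes (adjusted p = 0.81) passed, and the medians of the housekeeping and endothelial lists turned with the scaling. Mesenchymal and receptor lists had a median and a mean of opposite sign. In all, 1852 genes changed in shNS, 890 higher and 962 lower, 1476 of them by at least 1.5-fold.

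**Figure D3:**
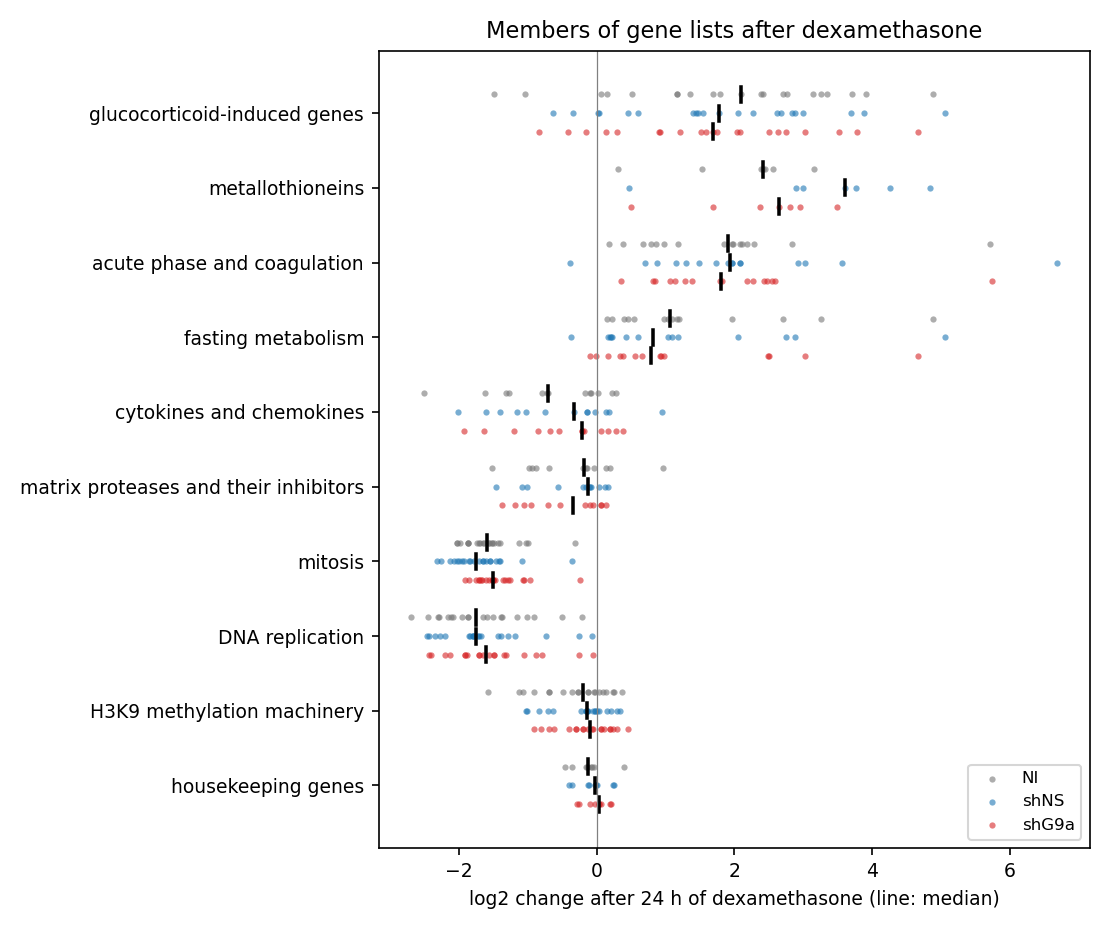
Log2 change after 24 h of dexamethasone for each measured member of gene lists in NI, shNS and shG9a (points), with the median as a line. Medians of the mitosis list were -1.60, -1.74 and -1.51, and those of the glucocorticoid-induced list 2.10, 1.78 and 1.69.

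Dexamethasone with the G9a hairpin shows the response at lowered EHMT2. SERPINA3 (5.73 ± 0.41, adjusted p = 3.9e-08, 3 arrays against 3) and CIDEC (4.66 ± 0.37, adjusted p = 1.1e-07) again rose most, followed by ANPEP (4.05 ± 0.17), CIDECP1 (3.81 ± 0.29), MAOA (3.78 ± 0.17) and ALOX5AP (3.74 ± 0.28). TSC22D3, which encodes the glucocorticoid-induced leucine zipper (3.52 ± 0.33), and MT1X (3.49 ± 0.38) also rose. The carboxypeptidase CPA4 fell most (-2.69 ± 0.63, adjusted p = 0.0079), with E2F7 (-2.65 ± 0.27), DTL (-2.57 ± 0.35), ERCC6L (-2.54 ± 0.30) and the replication genes MCM10 (-2.52 ± 0.32), CDC45 (-2.43 ± 0.29), EXO1 (-2.42 ± 0.29) and GINS2 (-2.40 ± 0.33). EHMT2 (0.09 ± 0.15), EHMT1 (-0.07 ± 0.20) and NR3C1 (-0.05 ± 0.17) did not pass.

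In shG9a 16 of 21 glucocorticoid-induced genes rose (16 adjusted over the list alone), including MAOA (3.78 ± 0.17), ANGPTL4 (3.03 ± 0.20) and ZBTB16 (at least 4.83-fold from not detected). For glucocorticoid-induced genes camera gave adjusted p = 4e-19, and adjusted p = 0.0071 with an estimated correlation. Acute phase genes rose in 11 of 16 cases (15 over the list alone), as in C3 (2.27 ± 0.26), SAA1 (2.59 ± 0.31) and LBP (2.54 ± 0.32; adjusted p = 1.6e-13). Metallothioneins rose in 6 of 7 cases (7 over the list alone), as in MT1H (2.81 ± 0.22) and MT1G (2.96 ± 0.35; adjusted p = 4.6e-12), and fasting metabolism genes in 8 of 14 (9 over the list alone), as in ACSL1 (2.48 ± 0.21) and the kinase PDK4 (2.51 ± 0.47; adjusted p = 1.8e-09). Mitosis genes fell in 21 of 22 cases (21 over the list alone), with CDK1 (-1.75 ± 0.21), AURKB (-1.91 ± 0.24) and MKI67 (-1.71 ± 0.22; adjusted p = 1.4e-25), and DNA replication genes in 18 of 20 (18 over the list alone), with MCM5 (-2.13 ± 0.24) and POLE2 (-1.87 ± 0.21; adjusted p = 3.2e-23). Members of the list of matrix proteases and their inhibitors fell in 4 of 12 cases (6 over the list alone; adjusted p = 0.0019). They were MMP3 (-1.18 ± 0.19), PLAUR (-1.06 ± 0.18), PLAT (to not detected) and MMP10 (at least 1.54-fold lower). Sodium and fluid transport genes rose in 3 of 10 cases (3 over the list alone), SCNN1B (3.11 ± 0.19), SCNN1G (at least 7.84-fold from not detected) and SGK1 (0.90 ± 0.21; adjusted p = 0.0043). These 8 lists kept their calls with an estimated correlation, at adjusted p = 0.038 or lower.

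Cholesterol synthesis genes TM7SF2 (0.99 ± 0.25) and LSS (0.79 ± 0.23) rose in shG9a, 2 of 15 (4 over the list alone; adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation). Cytokines CXCL5 (-1.63 ± 0.17), CCL2 (-1.92 ± 0.45), PTGS2 (-1.20 ± 0.31) and LIF (-0.54 ± 0.17) fell, 4 of 13 (5 over the list alone; adjusted p = 0.015, and adjusted p = 0.11 with an estimated correlation). In lists without a call, HSD11B1 rose at least 9.68-fold from not detected, IFIT1 (1.29 ± 0.25) and CDH1 (1.16 ± 0.25) rose, and GDF15 (-1.73 ± 0.24), CRY1 (-1.23 ± 0.17) and DNMT1 (-0.91 ± 0.15) fell. SFTPD (2.90 ± 0.27) and ABCA3 (0.83 ± 0.21) rose in a surfactant list whose median of -0.02 turned with the scaling, as did the medians of the serine and housekeeping lists; DCN, a fibroblast marker, rose at least 1.37-fold from not detected. Median, mean and test were not all of 1 sign for the surfactant, mesenchymal, circadian, p53, MAP kinase, receptor and housekeeping lists. In shG9a 1271 genes changed, 606 higher and 665 lower, 1077 of them by at least 1.5-fold.

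The responses of the 3 populations can be set side by side because these comparisons share no array. They are not equally separate, however. The shNS and shG9a arrays lie on the same slides, which pair them, while the NI arrays with dexamethasone lie on other slides. Slide effects can therefore raise the overlap and correlation between the hairpins and lower those with NI. A closer likeness of the hairpin responses cannot be told from this layout. The 941 genes called in all 3, such as SERPINA3, MAOA and CDK1, had the same direction in each, 447 higher and 494 lower. Of the genes higher in shG9a, 488 of 606 were also called higher in shNS, and of those lower 572 of 665, against 45.9 and 54.4 for independent lists. Between NI and shNS 699 genes were shared higher and 687 lower, and between NI and shG9a 523 and 537. Across genes, which are not independent replicates, the changes correlated at Pearson 0.887 and Spearman 0.756 between shNS and shG9a, with a slope of 0.772 for shG9a on shNS. They correlated at 0.788 and 0.665 between NI and shNS and at 0.787 and 0.663 between NI and shG9a.

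**Figure D4:**
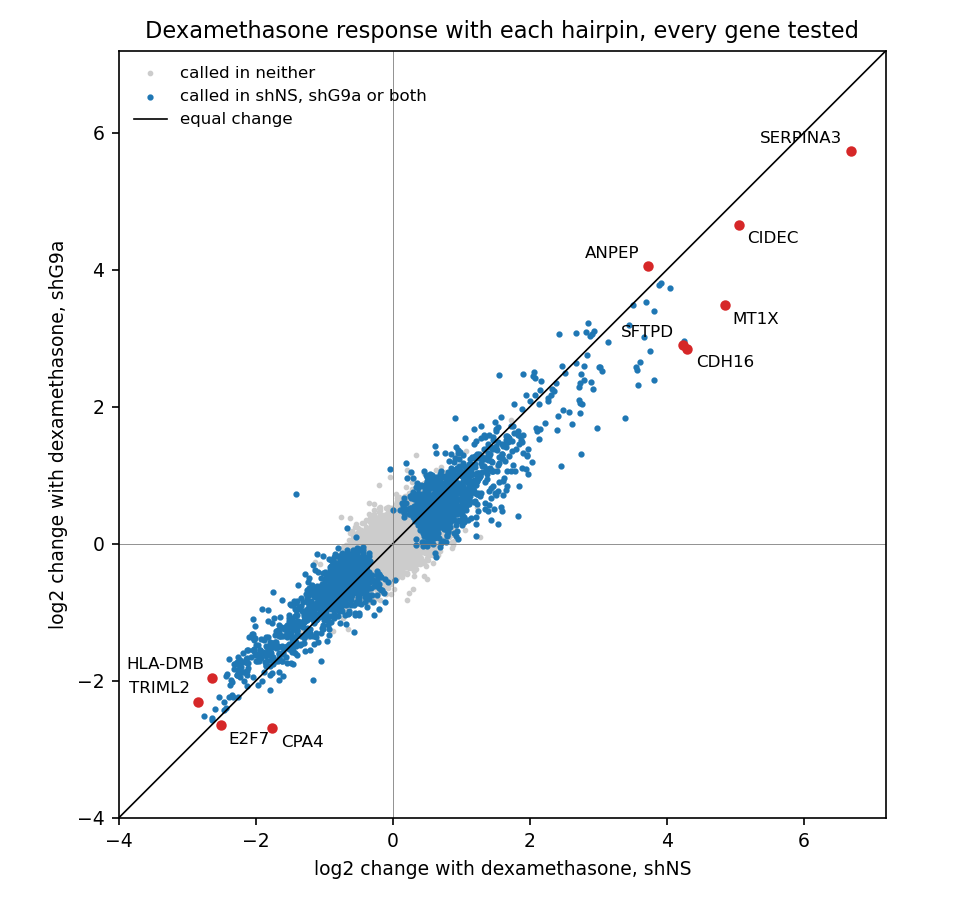
Log2 change with dexamethasone in shNS (horizontal) and shG9a (vertical) for every gene tested, with the line of equal change and genes called in shNS, shG9a or both in colour; CDH16, plotted at its fitted value, was not detected at 0 h in shNS. The changes correlate at Pearson 0.887 with a slope of 0.772 for shG9a on shNS, which spread in the shNS changes also lowers.

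Whether the dexamethasone response depends on G9a was tested as the difference between the changes in shG9a and in shNS. No gene passed the threshold over all genes. Among list members, the rise read lower with shG9a for the metallothioneins MT1X (-1.36 ± 0.53), MT1G (-1.30 ± 0.50), MT2A (-1.30 ± 0.44) and MT1H (-0.95 ± 0.31) and for surfactant protein D, SFTPD (-1.33 ± 0.38). HSD11B2 (-1.44 ± 0.76), LBP (-1.02 ± 0.45), the cyclin-dependent kinase inhibitor CDKN1C (-0.86 ± 0.33) and SGK1 (-0.65 ± 0.29) lay in the same direction. CDK1 (0.57 ± 0.30) and CCNA2 (0.52 ± 0.29), whose fall was smaller, ETV4 (0.78 ± 0.35) and PTGS2 (0.81 ± 0.43) lay in the other. EHMT2 (0.10 ± 0.21), EHMT1 (-0.07 ± 0.29) and NR3C1 (0.12 ± 0.24, a second probe at -0.46) did not pass. The metallothionein list was lower (0 of 7 members past the threshold over all genes, 5 lower over the list alone, median -0.95, camera adjusted p = 2.9e-07), and the mitosis list higher (0 of 22 and 0 over the list alone, median 0.26, adjusted p = 0.0012). With an estimated correlation neither call was kept (adjusted p = 0.43 and adjusted p = 0.82). The metallothionein median for shG9a against shNS was 0.72 at 0 h and -0.17 at 24 h (adjusted p = 0.34 at 24 h), so that most of the lower rise lay in the level before treatment. In the limma test over all 11750 genes 0 were called, 208 had an unadjusted p under 0.05 against 587.5 by chance, and the smallest adjusted p was 0.14. Other splits of the hairpin arrays gave a median of 577 such genes. A count so far below chance is not evidence of an equal response, because this fit leaves out the slide, which pairs the hairpin arrays. In simulated data of this size, drawn without slide effects, 44.8% of 2-fold and 89.4% of 4-fold differences were called.

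Among genes that responded in uninfected cells by at least 1.5-fold, 1171 induced and 1020 repressed, only the mitochondrial carrier gene SLC25A18 differed in its response between the hairpins when adjusted over these genes alone. It was detected on no array at 0 h and rose at least 4.20-fold in shNS and at least 1.67-fold in shG9a. The difference of -1.32 ± 0.22, negative on all 3 slides (adjusted p = 0.026 over the selected genes and 0.14 over all), therefore rests on its level at 24 h. With the slide as a block 2 genes passed, and with the compared groups alone in the fit 0. The call was lost without any single hairpin array at 0 h and without array 1 of either hairpin at 24 h (0 genes each), and 3 genes passed without NI array 2, shG9a array 2 or shNS array 3 at 24 h. At an unadjusted p under 0.05, the response read smaller with shG9a for 46 induced genes and larger for 8, and smaller for 22 repressed genes and larger for 3, where chance would give 58.6 induced and 51 repressed genes in either direction. These counts too come from the fit that leaves out the slide. Fisher's exact test of the direction of the difference by the direction of the response, which takes genes as independent, gave a two-sided p = 4.4e-10. By sign alone 59.4% of induced and 71.3% of repressed genes had the smaller response with shG9a. The median difference was -0.06 for induced and 0.16 for repressed genes. The selection rests on NI, where slide and dexamethasone cannot be told apart. Some genes counted as induced or repressed may therefore have been selected for the slide. Of 92 genes called in NI whose change was significantly lower than in shNS, 84 had no call in shNS.

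Averaged over the induced genes of this selection, the response per slide was 0.81 ± 0.07 (SD, n = 3 slides) in shNS and 0.73 ± 0.15 in shG9a, 90.1% of it (exact permutation test, two-sided p = 0.6). Repressed genes averaged -0.83 ± 0.04 (SD, n = 3 slides) and -0.69 ± 0.13, or 82.3% (exact permutation test, two-sided p = 0.2). With 3 slides each the smallest possible p is 0.1. This test leaves out the pairing of the hairpins by slide. The averages also include any genes that were selected in NI for the slide and not for dexamethasone. The differences per slide averaged 0.15 ± 0.08 (SD, n = 3 slides) for repressed and -0.08 ± 0.08 for induced genes, and were not tested as pairs. The repressed genes responded less with shG9a on each of the 3 slides, with differences of 0.06 to 0.23; those of the induced genes ranged from -0.15 to 0.01.

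The hairpins were compared without dexamethasone to show which genes differ with the G9a hairpin in unstimulated cells. Since 1 hairpin was used, such a difference need not come from G9a. Besides EHMT2, the genes lower with shG9a were LCN2, the iron-binding lipocalin (-1.85 ± 0.33, adjusted p = 0.034, 3 arrays against 3), and a group of ZNF genes: ZNF256 (-1.14 ± 0.20), ZNF350 (-1.04 ± 0.18), ZNF502 (-0.96 ± 0.18), ZNF559 (-0.90 ± 0.17), ZNF274, which recruits a methyltransferase to other zinc finger genes (-0.83 ± 0.15), and ZNF671 (-0.83 ± 0.16). Higher were the protease inhibitor SERPINB7 (1.60 ± 0.26), the tubulin TUBAL3 (1.27 ± 0.17), the cytokine receptor chain IL20RB (1.13 ± 0.20), the bile acid binding protein FABP6 (1.11 ± 0.20), GKN1 (0.93 ± 0.12) and PODXL (0.86 ± 0.16). All 14 had the same direction on each of the 3 slides. Metallothioneins were higher as a list (0 of 7 past the threshold over all genes, 4 over the list alone), with MT2A at 1.30 ± 0.31, MT1G at 1.15 ± 0.35 and MT1X at 0.98 ± 0.38. For metallothioneins the camera result was adjusted p = 3.6e-06, and adjusted p = 0.27 with an estimated correlation. Acute phase genes were lower as a list, with LCN2 past the threshold (1 of 16, 2 over the list alone) and ceruloplasmin CP at -1.34 ± 0.32, while SERPINA3 stood at 1.16 ± 0.41. For acute phase genes the list test gave adjusted p = 0.032, and adjusted p = 0.55 with an estimated correlation. No H3K9 methylation gene of the list (0 of 20, 0 over the list alone) and none of the 8 cancer-testis genes (0 over the list alone) passed; MAGEA6 read 0.30 ± 0.22.

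In this comparison 6 genes were higher and 8 lower, and 479 had an unadjusted p under 0.05 against 587.5 by chance, in a fit that leaves out the slide. With the compared groups alone in the fit 0 genes were called. With the slide as a block 15 genes were called and 10 of the 14 were kept; EHMT2 (0.066), PODXL (0.066), ZNF671 (0.066) and ZNF274 (0.087) lost their adjusted p. Without the shNS array 1, 2 or 3 the count was 2, 5 and 5, and without the shG9a array 1 or 2 it was 2 and 3. The medians of the fasting, H3K9 and endothelial lists turned with the scaling.

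After 24 h with dexamethasone the comparison shows which genes of treated cells differ between the hairpins, with the same limit. Lower with shG9a were the transcription factor SPDEF (-2.05 ± 0.36, adjusted p = 0.02, 3 arrays against 3), LCN2 (-2.01 ± 0.33), the anion channel BEST2 (-1.61 ± 0.22), the fatty acid activating enzyme ACSL5 (-1.57 ± 0.31), CILP (-1.40 ± 0.27), the tyrosine catabolic enzyme HPD (-1.33 ± 0.16), CDH16 (-1.33 ± 0.20) and SLC25A18 (-1.32 ± 0.16, adjusted p = 6.4e-04). Among the higher genes were DAW1 (2.36 ± 0.45), SERPINB7 (1.51 ± 0.26), IL20RB (adjusted p = 0.0018), the thromboxane synthase TBXAS1 (1.27 ± 0.23), PRUNE2 (1.17 ± 0.18) and TUBAL3, which was not detected in shNS and was at least 1.88-fold higher (adjusted p = 0.01). SFTPD stood at -1.32 ± 0.27 (adjusted p = 0.055) and CDKN1C at -1.05 ± 0.23 (adjusted p = 0.091). Both passed with the slide as a block (adjusted p = 0.013 and 0.024), with ranges over the alternatives of 0.0089 to 0.38 and 0.012 to 0.47. The genes LCN2, IL20RB, SERPINB7 and TUBAL3 were called at both times in the same direction.

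Acute phase genes were lower with shG9a at 24 h as a list (LCN2 past the threshold, 1 of 16, and 3 over the list alone), with CP at -1.40 ± 0.32, C3 at -0.86 ± 0.26 and LBP at -0.86 ± 0.32. C3 did not pass over all genes (adjusted p = 0.39) but did with the slide as a block (adjusted p = 0.030, with a range of 0.030 to 1.0 over the alternatives). For acute phase genes camera gave adjusted p = 3.7e-05, and adjusted p = 0.29 with an estimated correlation. Serine synthesis and amino acid response genes were higher (0 of 19 past the threshold, 2 over the list alone), with MTHFD2 at 0.89 ± 0.26, ASNS at 0.93 ± 0.28 and PSAT1 at 0.68 ± 0.25. For serine genes the camera result was adjusted p = 5.6e-05, and adjusted p = 0.52 with an estimated correlation. MAP kinase feedback genes were higher (0 of 18, 3 over the list alone), with DUSP4 at 0.79 ± 0.18, ETV5 at 0.63 ± 0.16 and ETV4 at 0.82 ± 0.25. For MAP kinase genes the list test gave adjusted p = 9.5e-04, and adjusted p = 0.29 with an estimated correlation. The mitosis list was higher (0 of 22, 0 over the list alone), with CDK1 at 0.42 ± 0.21. For mitosis genes camera gave adjusted p = 0.0041, and adjusted p = 0.80 with an estimated correlation. The 4 fibroblast markers were higher (0 past the threshold, 1 over the list alone), with THY1 at 0.81 ± 0.27 and DCN at 0.42 ± 0.20. For fibroblast markers the camera result was adjusted p = 0.0041, and adjusted p = 0.29 with an estimated correlation. Cytokines, with CXCL8 at 1.10 ± 0.40 and CXCL1 at 0.80 ± 0.33, had adjusted p = 0.033 (0 of 13, 0 over the list alone; 0.058 with the slide as a block and adjusted p = 0.29 with an estimated correlation). Mesenchymal genes, with ITGA5 at 0.64 ± 0.21 and AXL at 0.45 ± 0.26, had adjusted p = 0.037 (0 of 12, 0 over the list alone; adjusted p = 0.77 with an estimated correlation). Medians of the epithelial, p53, autophagy and housekeeping lists turned with the scaling.

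At 24 h 20 genes differed, 7 higher and 13 lower, each with the same direction on all 3 slides, and 559 had an unadjusted p under 0.05; median scaling gave 7 higher and 8 lower. With the slide as a block 45 genes were called, among them all 20. Array weights gave 74, and the compared groups alone in the fit 0. The count was 8 without array 1 of either hairpin at 24 h and 13 without shG9a array 2. Across genes the differences at 0 h and 24 h, which share no array but lie on the same slides, correlated at Pearson 0.343 and Spearman 0.189. All 14 of the 14 genes called at 0 h had the same sign at 24 h. Of the 20 called at 24 h, 17 had it at 0 h, but some of these differences lay near 0 in undetected genes. BEST2 (-0.06) and, outside the naming rule, CACNA2D3 (-0.03) and ENTPD2 (-0.006) were detected on no hairpin array at 0 h. For such genes the sign at 0 h does not show a difference before treatment.

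**Figure D5:**
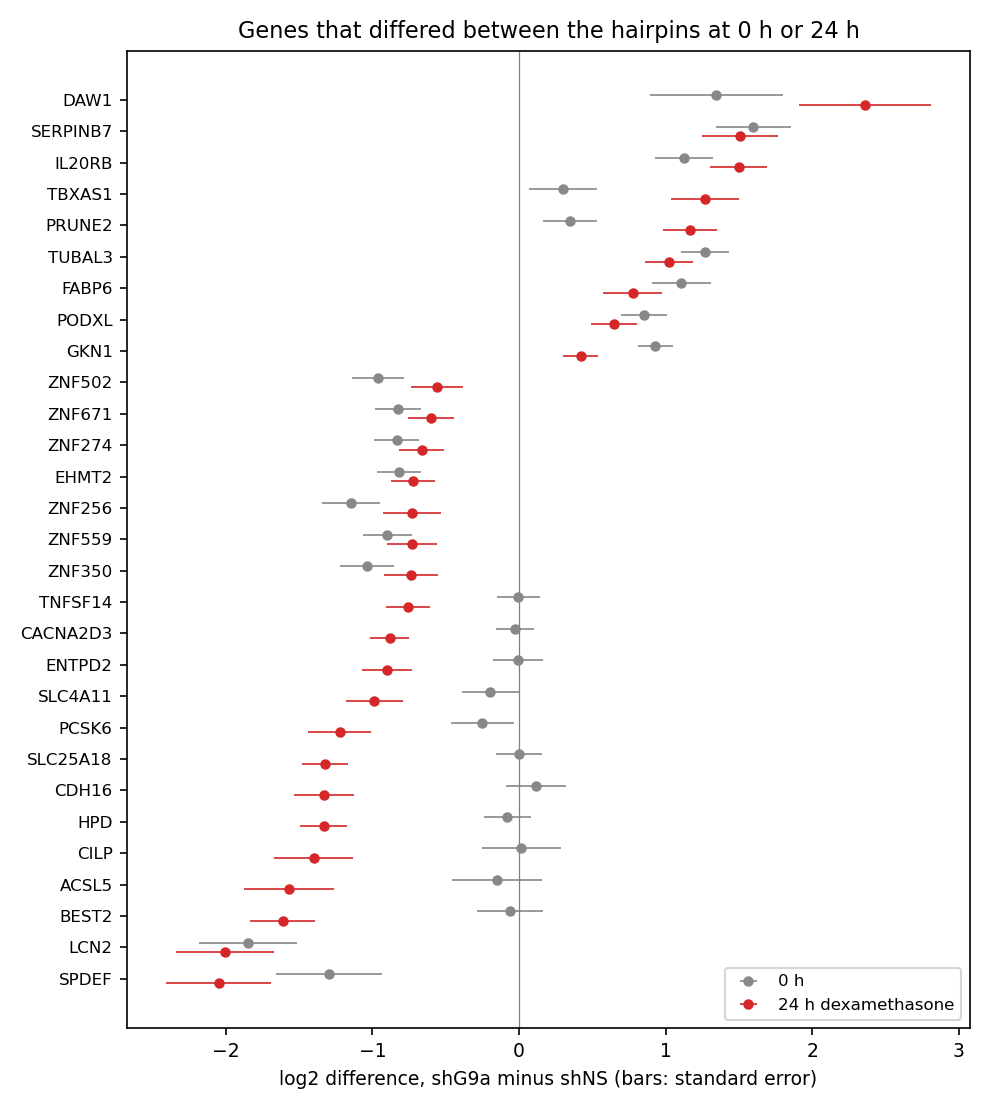
Log2 difference of shG9a minus shNS at 0 h (grey) and after 24 h of dexamethasone (red), with standard errors, for genes among those called at either time. LCN2 is lower at both times (-1.85 and -2.01), while SLC25A18, which was not detected at 0 h, is lower at 24 h (-1.32).

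The non-silencing hairpin was compared with uninfected cells at 0 h to show what infection and the control hairpin changed together. ANXA10, an annexin (1.29 ± 0.20, adjusted p = 0.038, 3 arrays against 3), and SPATA18, which encodes a mitochondrial quality control protein (1.18 ± 0.19, adjusted p = 0.038), were higher in shNS on all 3 slides, and 0 genes were lower in the limma test (687 genes in either direction at an unadjusted p under 0.05). Over the alternatives the adjusted p ranged from 0.0026 to 0.65 for ANXA10 and from 0.0026 to 0.53 for SPATA18, and without any single array of either group no gene was called. EHMT2 (-0.22 ± 0.15), EHMT1 (-0.15 ± 0.20) and NR3C1 (0.16 ± 0.17) did not pass. Cholesterol synthesis genes were lower as a list (0 of 15 past the threshold, 0 over the list alone), with MVD at -1.06 ± 0.40, HMGCS1 at -0.63 ± 0.24 and LSS at -0.59 ± 0.23. For cholesterol genes the list test gave adjusted p = 5.6e-04, and adjusted p = 0.36 with an estimated correlation. Targets of p53 were higher (0 of 18, 1 over the list alone), with TP53INP1 at 1.14 ± 0.31 and MDM2 at 0.67 ± 0.22. For p53 targets camera gave adjusted p = 0.018, and adjusted p = 0.36 with an estimated correlation. Mitosis genes were lower (0 of 22, 0 over the list alone), with BUB1B at -0.47 ± 0.25 and CDC20 at -0.39 ± 0.24. For mitosis genes the camera result was adjusted p = 0.022, and adjusted p = 0.74 with an estimated correlation. Interferon-stimulated genes did not pass (0 of 19, 0 over the list alone, adjusted p = 0.12), with IFIT2 at 0.54 ± 0.22 and MX1 at 0.45 ± 0.19. Cytokines, of which IL32 was lower over the list alone (0 of 13 over all genes), had adjusted p = 0.069, 0.028 with the slide as a block, and adjusted p = 0.36 with an estimated correlation. Medians of the glucocorticoid-induced, matrix, mesenchymal and receptor lists turned with the scaling.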

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

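The test of the low-stringency controls, the test of other probes of the same genes and both tests of differences already present without dexamethasone were chosen after the results they concern were seen, as was the count over splits that part every slide for the difference of responses.

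The dexamethasone change differed between NI and shNS for 108 genes, 94 of them lower in NI and 14 higher, and between NI and shG9a for 134 genes, 82 of which were in both sets. The 94 lower genes include VN1R2 and PGAM4, 92 of them were called in NI, and 84 of these had no call in shNS. With the slide as a random block 127 genes differed, of which 107 were among the 108. These comparisons are tests of the difference itself, but the NI arrays at 24 h fill slides 1 and 5.

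A response to dexamethasone that the hairpin vector changes was set against weaker binding on these slides. Against the former, 1 of 9 other probes of 7 of the lower genes showed at least 50% of the difference, compared with 288 of 457 (63.0%) other probes of genes called in shNS (Fisher's exact test, p = 0.0024). Low-stringency controls, whose targets match them imperfectly, fell by 1.25 on the log2 scale beyond the hybridisation controls on slides 1 and 5 (highest array at -1.82, against a lowest array at -0.88 on slides 2 to 4). Pseudogenes made up 10 of the 94 lower genes (10.6%) and 81 of 11656 others (0.695%; Fisher's exact test, p = 2.5e-09). Both values are consistent with a loss of cross-hybridising signal on slides 1 and 5; the part of the falls in NI that dexamethasone itself causes stays open.

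At 24 h, 22 genes induced in NI were lower with shG9a than with shNS and 4 higher when adjusted over the selected genes, while 8 repressed genes were higher and 1 lower (Fisher's exact test, p = 1.6e-04, which takes genes as independent). BEST2, not detected at 0 h, rose at least 8.83-fold in shNS and at least 2.88-fold in shG9a, and CDH16, ACSL5 and SFTPD lay the same way; TBXAS1, a repressed gene, fell by 1.92 and by 0.94 on the log2 scale. The 30 genes of the pattern compare with 0 in the highest of the other splits of the 6 arrays, which are too few for a share under 0.05.

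The normalisation was argued against as the whole cause, since the direction held with median scaling (19 and 3 induced genes lower and higher, 3 and 0 repressed genes higher and lower; Fisher's exact test, p = 0.0087). Differences between slides were also weighed, with the slide as a block (Fisher's exact test, p = 1.9e-04). Each slide holds both hairpins, so this block leaves every difference as it was and changes only which genes pass. The test therefore cannot decide whether the direction comes from the slides. Medians over the selected genes had the same sign on each of the 3 slides but were small. They were -0.050, -0.050 and -0.036 for induced and 0.135, 0.093 and 0.015 for repressed genes. A difference already present without dexamethasone can show only in genes detected at 0 h, and of the 22 induced genes 7 were detected on no hairpin array at 0 h and 6 on some of them. The other 9 had a median of 19.9% of their 24 h difference at 0 h (-4.48% to 82.7% over 1000 resamples), with LCN2 at 92.0% and CD38 at 82.7%. For the 8 repressed genes, all detected, the median was 49.2% (19.6% to 91.1%). In both classes a difference before treatment and a changed response cannot be told apart. The direct test of the difference of responses called SLC25A18 alone, and effects of the hairpin other than on EHMT2 stay open, since 1 hairpin was used.

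SLC25A18 was the 1 gene called for G9a dependence (difference -1.32, negative on all 3 slides), and as it was not detected at 0 h the difference rests on its level at 24 h. For G9a dependence 20 of 100 drawn splits gave at least as many genes, with 79 in the highest against 1, so that chance cannot be excluded. For the difference of responses over all genes the real count was 0, which all 100 splits reached, with 303 in the highest. Of the 32 splits that part the hairpins on every slide at both times, 8 gave as many G9a-dependent genes. The highest of them, with 40 G9a-dependent genes and 66 over all genes, exchanges the hairpins on every slide at 1 time, and so adds up the hairpin differences of the times. Splits of this kind contain real differences between the hairpins, and the counts above do not show by themselves that other arrays share a structure. For dexamethasone in NI the real split alone of 35 gave 3112 genes, with 1150 in the highest other, a share under 0.05. The real split also parts the slides, so this count says nothing of dexamethasone apart from the slide. For the remaining comparisons the 10 splits are too few for a share under 0.05: 1852 genes against 2 in the highest other split in shNS, 1271 against 1 in shG9a, 20 against 0 for the hairpins at 24 h and 2 against 0 for shNS against NI, with 1 split as large in each. At 0 h 2 of the 10 splits gave as many genes as the hairpins, and 68 in the highest other split against 14. That split set shNS and shG9a arrays of slide 2 and the shNS array of slide 4 against the rest, so that it leaves arrays of a slide together. Among the splits that part every slide, the highest other gave 0 genes, and with the slide as a block the hairpins gave 15.

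Among 22 quantities tested in the 4 NI arrays at 24 h, namely named genes and 3 measures of the whole array, 3 had an array far from the others, where 1.1 would be so by chance: PLA2G10 and MAD2L1 on array 2, with 0.837 and 0.865 of the whole range between that array and its neighbour, and MAOA on array 1 (0.840). Probes that list no gene also responded to dexamethasone. Of 3235 such probes, 852 changed in NI (376 higher, 476 lower), where slide and treatment coincide, 323 in shNS (173 higher, 150 lower) and 236 in shG9a (130 higher, 106 lower), and 0 differed between the hairpins in their response in the limma test.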

How the results depend on the processing

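Of 841 results for named genes, 303 were past the threshold and 215 of these kept their direction and their side of it under every alternative run, and none reversed; of 44 list results past the threshold none reversed. Named calls kept under every alternative numbered 81 of 99 for dexamethasone in NI, 72 of 92 in shNS and 62 of 81 in shG9a, and 0 of 14, 0 of 15 and 0 of 2 for the hairpins at 0 h, at 24 h and for shNS against NI. The counts of dexamethasone genes stayed within 1.5 times, at 1308 to 2558 in shNS and 852 to 1848 in shG9a. In NI this held except for 6379 genes with array weights and 1991 with the arrays of slide 5 alone, an alternative chosen after seeing the data. The difference in mean response between hairpins stayed within -0.12 to -0.04 for induced and 0.11 to 0.19 for repressed genes, and the correlations of dexamethasone changes within 0.721 to 0.806, 0.718 to 0.809 and 0.824 to 0.903.

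The slide as a fixed replicate block could not be fitted for dexamethasone in NI and was not run there. It moved the count of genes at 24 h between the hairpins from 20 to 45 and the G9a-dependent genes from 1 to 2, and EHMT2 at 0 h (-0.82) no longer passed (adjusted p = 0.066, within 0.011 to 0.999 over the alternatives). It changed no other count by more than 1.5 times. As a random block (correlation 0.232) the slide gave 2 genes for the difference of responses, 24 at 0 h, 67 at 24 h, 6 for shNS against NI and 4 for G9a dependence, and EHMT2 at 24 h (-0.73) passed (adjusted p = 0.019, within 0.019 to 0.267).

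Array weights gave 5 genes at 0 h, 74 at 24 h, 37 for shNS against NI and 0 for G9a dependence, with EHMT2 at -0.84 at 0 h (adjusted p = 0.120) and -0.66 at 24 h (adjusted p = 0.0235). With the compared groups alone in the fit, which leaves fewer arrays to estimate the spread, 0 genes were called at 0 h, at 24 h, for shNS against NI and for G9a dependence, and EHMT2 at 0 h (-0.82) had adjusted p = 0.999. Without background correction 5 genes were called at 0 h, 0 for shNS against NI and 0 for G9a dependence, and EHMT2 at 0 h was -0.47 (adjusted p = 0.145). Without the detection filter 2 were called at 0 h and 0 for shNS against NI, with EHMT2 at -0.82 (adjusted p = 0.051). With all detected probes 0 were called for shNS against NI. The difference at 24 h in place of the difference of responses gave 35 genes, of which 30 were induced genes lower or repressed genes higher in level with shG9a, which need not be a smaller response. Except where fewer arrays or more tests give it, the cause was not tested.

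With each array left out in turn, the counts ranged from 2 to 12 at 0 h, 8 to 18 at 24 h, 0 to 1 for the difference of responses (1 without shNS array 2 at 24 h) and 0 to 3 for G9a dependence. For shNS against NI the lowest and highest were 0 and 0. At 0 h the count fell furthest without array 1 of shNS or of shG9a (2 each), and at 24 h without array 1 of shNS or of shG9a (8 each). EHMT2 ranged from -0.91 to -0.68 at 0 h and from -0.84 to -0.60 at 24 h.

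With an estimated correlation camera called 1 list in NI, 7 in shNS and 0 each for the difference of responses, the hairpins at 0 h and at 24 h and shNS against NI. The fry test, which does not compare a list with other genes, called 17 in NI, 16 in shNS, 14 in shG9a and 0 for each of the same 4 comparisons. The regular probes read only 1.82 to 2.10 times the negative controls in the median, which limits what dim probes can show.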

Other observations

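The group of ZNF genes was chosen after its values at 0 h were seen, while its tests were written before their own results.

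Of 244 ZNF genes, 36 were lower with shG9a than with shNS at 0 h at an unadjusted p under 0.05 and 2 higher (14.8% lower, against 1.78% of 11506 other genes). At 24 h, on other arrays, 28 were lower and 3 higher (11.5% against 2.10%). For the arrays at 24 h, which played no part in the choice of the group, camera gave p = 9.8e-07 (0.018 with an estimated correlation), and the median of the group was below 0 at both times under each scaling. Of the 36, 34 were below 0 at 24 h (median -0.45), and 21 were lower at both times.

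In shNS against NI at 0 h, 20 ZNF genes were higher and 1 lower, and this comparison shares the shNS arrays with that of the hairpins at 0 h. A rise in the control alone was therefore tested on the 28 genes lower at 24 h. At 0 h their median was -0.54 for shG9a against shNS, 0.33 for shNS against NI and -0.24 for shG9a against NI. For shG9a against NI the median was -0.33, -0.17 and -0.17 on the 3 slides, and 22 of 28 genes were below 0. The SE of 0.058 of this median was taken over genes, which are not independent, and is not a spread between arrays. The sign was the same on each slide, but the 28 genes were chosen for low shG9a against shNS at 24 h. The slide pairs the shG9a arrays of both times and not the NI arrays, so this choice can favour low shG9a values at 0 h. The test therefore cannot decide whether a rise in the control is the whole cause for these genes. Over all 244 ZNF genes the median at 0 h was -0.02 for shG9a against NI and 0.10 for shNS against NI. Camera gave p = 0.277 for shG9a against NI (0.560 with an estimated correlation) and p = 1.3e-04 for shNS against NI (0.0556). At an unadjusted p under 0.05, 15 were lower and 5 higher in shG9a than in NI, or 6.15% lower against 2.76% of other genes. For the whole group these values therefore do not argue against a rise in the control. Signal shared between similar probes stays open: 5 of 5 other probes (100%) of 4 of the genes were below 0 at 24 h, too few to decide. Of the ZNF genes with another ZNF gene as nearest protein-coding neighbour 34 of 129 were lower at 0 h, against 2 of 115 without (Fisher's exact test, p = 8.8e-09), and 27 against 1 at 24 h (Fisher's exact test, p = 2.1e-07). Both tests take genes as independent, which neighbours may not be, and the group was chosen from the values at 0 h. A candidate explanation is a fall of clustered ZNF genes with lowered EHMT2, but neighbours also resemble each other in sequence, so that shared probe signal could give the same picture.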
